A study of Mus musculus with 2 samples.

How the data were processed

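The data were 1 ChIP library made with an antibody to the HA tag and 1 input library, both from cultured mouse CD8+ T cells that carried a retrovirus with HA-tagged Bcl6 and GFP, per the labels' protocols. The ChIP library's peak list was the only table used. Bowtie2, Picard, MACS2 and ChIPseeker were used with the mm10 build, per the submitters' processing notes, which give no versions, settings or order of steps. Peak names in the deposited list carry a q threshold of 0.05, and the list comes from 1 ChIP library with no pooling. Whether the input served as control is not stated.

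For each peak the deposited list gives a score, which equals 10 times the −log10 q value without its decimals for all peaks but 1. It also gives the fold enrichment, a ratio of the summit signal to the local background of the peak caller, as the authors deposited it. The −log10 p-value and the −log10 q-value of the summit against that background were used as the authors deposited them. Starts in the deposited list count from 0 and are given here counted from 1. No peak was called again and no value was rescaled.

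The ChIP fragments at each summit and the background were computed from the deposited fold and −log10 p. The definitions of MACS2 were assumed, in which fold is the count plus 1 over the background plus 1 and p is the upper Poisson tail. A whole number of fragments matched both values within a relative tolerance of 0.0001 for 6053 of 6053 peaks, and for 1.32% when the p values were shuffled over peaks. The lowest background was 1.33 fragments, at 1983 peaks (32.8%). Of 4055 backgrounds clearly above it, with those just over it left out, 1836 were whole multiples of 0.892 within 0.02%. That step corresponds to 1 fragment of a control library scaled to the ChIP, with 1.12 control tags per ChIP tag. The other backgrounds lay on the finer step of such a fragment spread over a 10 kb window. At a fragment length of 126 bp 100% did, against a median of 6.49% over the lengths tried. The depth in reads is not stated for either library. No summit had more than 252 fragments, which equals 2 strands times the shortest peak of 126 bp. The precision at a summit was taken as the counting error of its fragments, a median of 21, with no ceiling on the count. On simulated data the fragment count was recovered for 496 of 500 peaks (99.2%).

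Genes were taken from a RefSeq table of the GRCm38.p6 assembly, which has the coordinates of mm10. It gives gene spans without strand, exons or transcription start sites, and no genome sequence was used. Several planned analyses were therefore replaced or left out. Promoters were replaced by 1 kb around either end of a protein-coding gene, the match on CpG content was dropped so that random lists were matched on gene length alone, and chromosome lengths were replaced by annotated spans. Sequence motifs, classes such as exon, intron and UTR, and the overlap with coding exons of Bcl6 were not analysed here.

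The 17 gene lists, with 356 entries for 317 genes, were fixed before the data were examined, as were the rule for named genes and the tests, apart from the replacements above. They cover stem-like and memory, exhaustion, effector and cytotoxic genes, genes repressed by Bcl6 in follicular helper T cells, Bcl6 targets in B cells, AP-1, NFAT and IRF factors, cytokine and JAK-STAT, T cell receptor signalling, Bcl6 co-repressors, cell cycle and DNA damage, glycolysis, chemokine receptors and homing, ribosomal proteins, and B cell, myeloid, hepatocyte and neuronal markers. All entries but 1, Iglc1, matched the table by symbol, and 34 genes are in more than 1 list. A list gene counted when a summit lay in the gene or within 10 kb of it. Each list was compared with 10000 random lists of protein-coding genes of the same size matched on 5 length bins, and the 2-sided p was doubled from the smaller tail and adjusted by Benjamini-Hochberg. On simulated data, 3 of 200 unchanged lists of 20 genes were called, and 200 of 200 lists in which 8 more genes had been given a peak. These calls used fewer random lists and a p without adjustment. Smaller excesses were not simulated, so the power to find them is not known. Lists were compared with each other by Fisher's exact test without the genes they share, a comparison chosen after the data were seen.

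The genes named were the nearest protein-coding gene of the 10 peaks with the smallest q value, by distance to the gene span. Bcl6, Prdm1, Tcf7, Pdcd1, Havcr2 and Tox were named whatever their values. For each list up to 4 members with a peak, taken by largest fold, and up to 3 without one, in alphabetical order, were named as well, except for a few that were left out. Promoter peaks, which the rule put before other peaks, could not be told from others. Gene ends in the text have no direction, and the distance to an end is that to the nearer end.

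Positions were compared with 1000 random placements of the same number of summits per chromosome within annotated spans, which model neither mappability nor open chromatin. Fold near gene ends was compared by a permutation test over peaks with 100000 resamples. The alternatives chosen before the data were examined were stricter q and fold thresholds and other choices of peaks for the number of peaks, and, for the lists, 50 kb around the gene, the gene body alone, the 3026 peaks of smallest q and no matching of random lists. All results at gene ends, with their other distances, peaks, genes and overlaps, were set up after the data were seen, in place of promoters. Finer length bins, 1 member per locus and only peaks over the lowest background were also added then. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.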

Results

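Binding of Bcl6, a zinc-finger repressor that directs follicular helper T cell and germinal centre B cell fates, was mapped in cultured mouse CD8+ T cells. Naive cells were activated with antibodies to CD3 and CD28 for 48 hours and infected with a retrovirus encoding HA-tagged Bcl6 and GFP, and GFP+ cells were sorted 2 days later. Chromatin was immunoprecipitated with an antibody to the HA tag in 1 library, and 1 input library came from cells of the same kind. The ChIP library had 6053 peaks on the mm10 build, of which 5938 lay on chromosomes 1 to 19, X and Y. With 1 library of each kind there was no replicate, so no difference between samples was tested, and each count below describes this ChIP library. At the median summit the ChIP had 21 fragments (quartiles 15 and 31). Intervals of fold enrichment are exact Poisson intervals on the ChIP fragments at the summit with the background held fixed, and intervals of shares are exact Clopper-Pearson intervals. Both are at the 95% level and cover counting error only. The Poisson intervals assume that the fragment count at a summit has no ceiling. Whether the highest count in the list is such a ceiling was not tested. If it is, folds and q values at summits close to it, such as that of Socs2, may be capped. Their intervals may then misstate the counting error, and the order of the strongest peaks may be affected.

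The ChIP against the background of the peak caller asked where tagged Bcl6 lay in the genome. The peak with the smallest q value lay inside Adpgk, an ADP-dependent glucokinase, at chromosome 9 from 59308180 to 59308942, with a fold enrichment of 85.7 (74.3 to 98.4). The next by q value lay outside any protein-coding gene, 30051 bp from Mier3, at a fold of 80.2 (69.3 to 92.4), and 58349 bp from Gbp6, an interferon-induced guanylate-binding protein, at 71.8 (62.3 to 82.5). A peak inside Bach2, a repressor that keeps T cells in a naive or memory state, had a fold of 78.0 (67.4 to 89.8) at chromosome 4 from 32319433 to 32320571. Atm, the kinase that starts the response to DNA double-strand breaks, held a peak of 73.7 (63.2 to 85.6), and Camk4, a calcium/calmodulin-dependent kinase, held a peak of 73.3 (62.8 to 85.1).

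The others among the 10 peaks with the smallest q values lay inside Rexo5 at a fold of 70.0, inside the aminopeptidase gene Aopep at 65.9, inside Ttc39c at 51.7, and 48066 bp from Spesp1 at 41.9. Most peaks were far weaker than these. The median fold over all peaks was 6.5 (quartiles 5.16 and 8.94), 1174 peaks (19.4%) had a fold of at least 10, and 249 (4.11%) had a fold of at least 20. The weakest signal that was called over the lowest background in the list was 9 fragments at a fold of 4.29. A list gene named below as without a peak had no summit called in it or within 10 kb. Weaker enrichment there is not excluded, and a called summit may lie just outside that window, as at Brca1, 10473 bp away.

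The series title puts the binding map in the context of CD8+ T cell fate in cancer, and 6 genes of that context were examined whatever their values. Pdcd1, which encodes the inhibitory receptor PD-1, held 4 peaks, with folds of 45.4 (39.1 to 52.4), 31.9 (26.6 to 37.8), 13.3 (11.1 to 15.8) and 6.55 (5.07 to 8.34). The strongest of them spanned 94041095 to 94041588 on chromosome 1. Havcr2, which encodes the inhibitory receptor TIM-3, had 4 peaks in the gene or 10 kb around it, led by 1 inside the gene at a fold of 36.4 (29.2 to 45.0) on chromosome 11 from 46466917 to 46467346. Prdm1, which encodes Blimp-1, a repressor that promotes terminal effector fate and opposes Bcl6, had 7 peaks with folds from 5.91 to 11.6 (8.36 to 15.8 for the strongest). Tox, a nuclear factor that sets the exhausted chromatin state, held 4 peaks inside the gene, none above a fold of 9.0 (5.67 to 13.7).

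Tcf7, which encodes TCF-1 of stem-like T cells, had no peak within 10 kb, and the nearest summit was 41230 bp from the gene. Bcl6 itself had 1 peak, at chromosome 16 from 23988505 to 23988699, with its summit 270 bp from an end of the gene and a fold of 6.92 (5.18 to 9.05). The retrovirus carried Bcl6 cDNA, whose reads also map to the endogenous gene, and the background under this peak was 6.52 fragments, against a lowest background of 1.33 in the list and a median of 3.6 at peaks within 1 kb of gene ends, of which 86.7% lay above that lowest value.

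**Figure D1:**
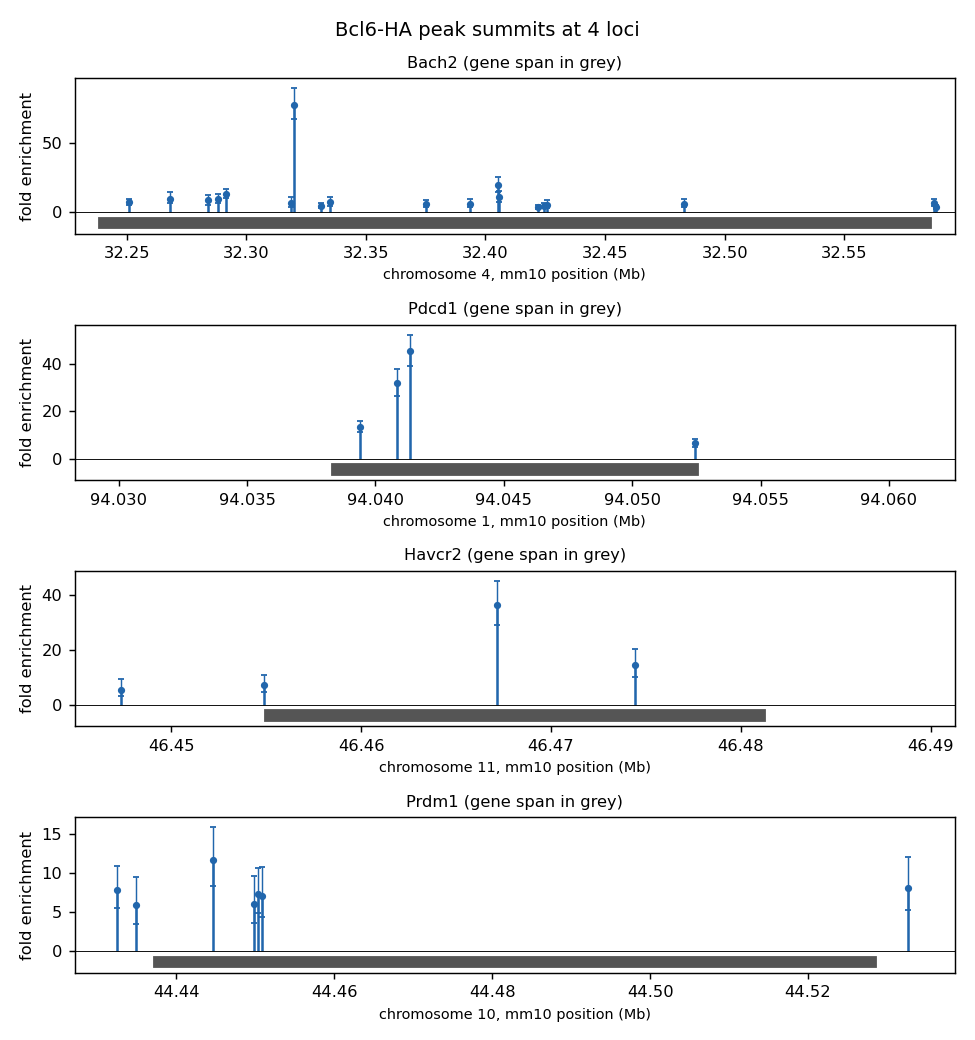
Fold enrichment of each Bcl6-HA peak at its summit (y axis) against mm10 position in Mb (x axis) at Bach2, Pdcd1, Havcr2 and Prdm1, with the gene span as a grey bar and bars for exact 95% Poisson intervals of the fold. The highest summit reaches a fold of 78.0 at Bach2, 45.4 at Pdcd1, 36.4 at Havcr2 and 11.6 at Prdm1.

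Gene lists fixed before the data were examined asked which programmes carried Bcl6-HA. Among 22 genes of stem-like and memory T cells, 18 had a peak in the gene or 10 kb around it, 6.04 times the mean of random lists matched on gene length. They were led by Bach2, by the survival gene Bcl2 at a fold of 49.3 (40.7 to 59.1) and by the quiescence factor Foxp1 at 31.5 (25.4 to 38.5). Exhaustion genes had a peak in 15 of 20, 5.79 times random, with Nfil3 at 34.1 (28.6 to 40.3) and the cytokine gene Il10 at 18.5 (16.1 to 21.1) after Pdcd1 and Havcr2. Genes that Bcl6 represses in follicular helper T cells had a peak in 16 of 20, 5.68 times random, among them Il2ra, which encodes the IL-2 receptor alpha chain, at 17.1 (12.3 to 23.3), and the nuclear receptor gene Rora at 13.1 (9.0 to 18.6).

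Effector and cytotoxic genes had a peak in 12 of 24, 4.85 times random, with Il12rb2, which encodes an IL-12 receptor chain, at 16.3 (12.5 to 21) and the chemokine gene Ccl3 at 15.9 (11.4 to 21.7) after Havcr2 and Il2ra. Ccl5, Cx3cr1 and Cxcr3 were among the members without a peak. In the stem-like list the members without one included Eomes and Id3 beside Tcf7, in the exhaustion list Cd160, Cd200r1 and Cd244a, and in the follicular helper list Id2 and Runx3.

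Chemokine receptor and homing genes had a peak in 16 of 24, at 7.53 times random the highest ratio of the 17 lists. Among them were the receptor genes Ccr2 at 12 (8.06 to 17.3), Ccr4 at 9.80 (7.67 to 12.4) and Ccr9 at 9.75 (6.33 to 14.4). T cell receptor signalling genes had a peak in 15 of 22, 4.79 times random, led by the phosphatase gene Ptpn22 at 16.7 (12 to 22.8), the ubiquitin ligase gene Cblb at 10.7 (7.02 to 15.7), Cd8a at 9.84 (6.39 to 14.6) and Bcl10 at 9.77 (6.51 to 14.1). Cd3e and Cd8b1 were among those without one. Cytokine and JAK-STAT genes had a peak in 15 of 24, 4.37 times random, led by the feedback inhibitor gene Socs2 at 25 (22 to 28.3). Stat2 followed at 14.3 (11.3 to 17.8), the kinase gene Jak2 at 13.7 (9.46 to 19.3) and the feedback inhibitor gene Cish at 10.6 (9.07 to 12.2), while Ifngr1, Il2rb and Il2rg had none.

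Targets of Bcl6 in B cells had a peak in 15 of 25, 4.64 times random, and the largest folds were at Bcl2, Socs2, the cyclin gene Ccnd2 at 19.5 (16.6 to 22.8) and Ccl3. The 15 include Bcl6 itself, whose peak may come from reads of the cDNA in the retrovirus. Arid3a, Cd74 and Cd80 of this list had none. Cell cycle and DNA damage genes had a peak in 12 of 27, 3.98 times random, with Cdkn2c, a CDK inhibitor gene, at 50.5 (41.8 to 60.4) and the kinase gene Cdk6 at 36.5 (29.6 to 44.7) after Atm. Brca1, Ccna2 and Ccnb1 had none. AP-1, NFAT and IRF factors had a peak in 6 of 20, 2.91 times random, led by Irf2 at 9.34 (6.17 to 13.6), Irf4 at 8.57 (5.33 to 13.2), Batf3 at 6.83 (5.02 to 9.09) and Nfatc1 at 6.66 (4.57 to 9.42), while Atf3, Batf and Fos had none.

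The remaining lists lay inside the range of random lists. Bcl6 co-repressors had a peak in 4 of 20, with Hdac9, Hdac4, Ncor1 and Zbtb32 at folds up to 6.0, and Bcor, Bcorl1 and Chd4 had none. Glycolysis genes had a peak in 4 of 20, with the hexokinase gene Hk2 at 11.2 (8.75 to 14.1), Hif1a at 7.72, and the glucose transporter genes Slc2a1 at 5.68 and Slc2a3 at 3.87, while Aldoa, Eno1 and Gapdh had none. Of 22 ribosomal protein genes only Rpl4 had a peak, at 4.80 (3.02 to 7.29), and Rpl10a, Rpl13 and Rpl18 were among those without. B cell lineage genes had a peak in 2 of 14 (Ebf1 and Bank1), neuronal genes in 1 of 18 (Gad2), myeloid genes in 0 of 15 and hepatocyte genes in 0 of 18. The exact intervals of the share reached up to 21.8% for the myeloid and 18.5% for the hepatocyte genes.

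Each list was set against 10000 random lists of protein-coding genes matched on 5 bins of gene length. The 2-sided p values were adjusted by Benjamini-Hochberg over the 17 lists. The adjusted p was 0.00038 for 9 lists, which rests on the smallest p that these random lists can give, 0.0002, and it was 0.032 for the AP-1, NFAT and IRF list. It was 0.56 or more for the other lists. When only the 1983 peaks over the lowest background were counted, the follicular helper, AP-1, cytokine and cell cycle lists no longer passed. With the 3026 peaks of smallest q the AP-1 list no longer passed (adjusted p 0.095), and with the gene body alone the cell cycle list did not (adjusted p 0.098).

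Stem-like and memory genes had a peak in 18 of 22 (81.8%) and effector genes in 12 of 24 (50%), which gave a p of 0.032 by Fisher's exact test, 2-sided, and 0.064 after adjustment over 4 comparisons. Exhaustion genes did not differ from effector genes past the threshold (14 of 19 against 11 of 23 without Havcr2, which is in both lists, exact p 0.12, adjusted 0.16), nor did stem-like from exhaustion genes (exact p 0.71, adjusted 0.71). The stem-like, exhaustion, effector and T cell receptor signalling lists together had a peak at 59 of 87 genes (67.8%), against 3 of 65 (4.62%) for B cell, myeloid, hepatocyte and neuronal genes (Fisher's exact p 1.4e-16, adjusted 5.6e-16). This gap narrowed in the gene body alone, to 39 of 87 (44.8%) against 3 of 65 (exact p 1e-08, adjusted 4e-08). Over the lowest background it was 22 of 87 (25.3%) against 3 of 65 (exact p 0.00067, adjusted 0.0027). The contrasts with effector genes depended on the window: within 50 kb 21 of 22 stem-like and 21 of 24 effector genes had a peak (exact p 0.61, adjusted 0.81), and in the gene body alone 14 of 22 and 5 of 24 (exact p 0.0063, adjusted 0.0084). For exhaustion against effector genes without Havcr2 the counts were 16 of 19 and 20 of 23 within 50 kb. In the gene body alone they were 12 of 19 and 4 of 23 (exact p 0.0039, adjusted 0.0078). These 4 comparisons were chosen after the data were seen and run over genes of 1 library, which are not replicates and were not matched on length between lists.

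**Figure D2:**
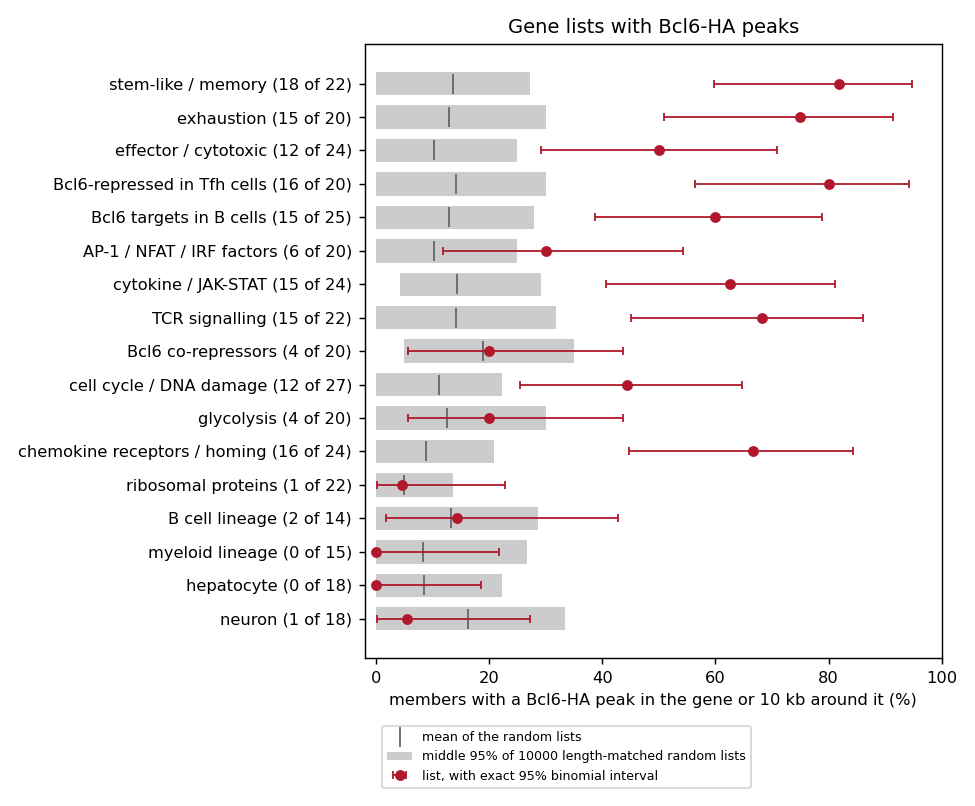
Share of each list's members with a Bcl6-HA peak in the gene or 10 kb around it (x axis, percent), as red points with exact 95% binomial intervals, against the mean (tick) and the middle 95% (grey bar) of 10000 random lists matched on gene length. Stem-like and memory genes stand at 81.8% and ribosomal protein genes at 4.55%.

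Close to gene ends, a summit lay within 1 kb of an end of the gene in 9 of 24 effector and cytotoxic genes (18.8 to 59.4%), among them Gzmb, which encodes granzyme B, at a fold of 14.2 (11.4 to 17.6) and Prf1, which encodes perforin, at 3.23 (2.22 to 4.54). These examples were chosen after their values were seen. Bcl6 targets in B cells had 7 of 25 (12.1 to 49.4%), Bcl6 itself among them. Exhaustion, follicular helper and homing genes had 4 members each, cell cycle genes 4 of 27, and stem-like and cytokine genes 3 each. The lists were not tested against each other. These 8 lists lay above the matched random lists at adjusted p values from 0.0011 to 0.03. T cell receptor signalling genes (2 of 22, adjusted p 0.18) and AP-1, NFAT and IRF factors (1 of 20, adjusted p 0.87) did not, nor did the ribosomal list (1 of 22, adjusted p 0.87), and the other 6 lists had none. With the 3026 peaks of smallest q the stem-like, follicular helper, cytokine and homing lists no longer passed, and over the lowest background only the stem-like, follicular helper and homing lists did. The stem-like list also failed at 500 bp and at a −log10 q of at least 5, the cell cycle list at 500 bp and the cytokine list at 3 kb, while the T cell receptor signalling list passed at 3 kb and with any base of the peak in place of its summit.

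Over the whole list, summits lay near protein-coding genes more often than at random positions. Inside protein-coding genes lay 50.6% of the 5938 summits (49.3 to 51.9), against a mean of 40.3% over 1000 random placements on the same chromosomes. Within 1 kb of an end of a protein-coding gene lay 353 summits, 5.95% (5.36 to 6.58), 1.95 times the random share of 3.05%. More than 100 kb from any gene end lay 15.3% (14.4 to 16.2), 0.42 of the random share of 36.4%. For each of these classes the 2-sided p was 0.002, the smallest that 1000 placements can give, while the share from 50 to 100 kb (14.3% against 13.5%) had a p of 0.07. A peak in the gene or 10 kb around it was found for 2572 of 21887 protein-coding genes (11.8%).

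**Figure D3:**
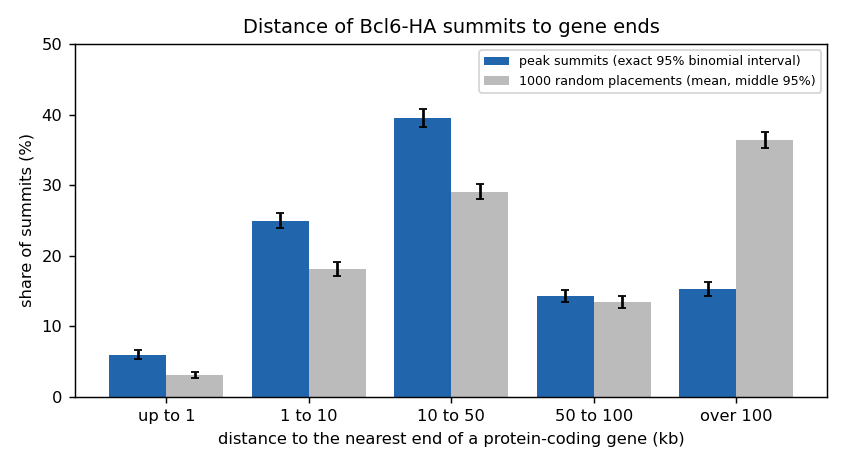
Share of Bcl6-HA summits (blue, exact 95% binomial intervals) and of 1000 random placements (grey, mean and middle 95%) by distance to the nearest end of a protein-coding gene in kb (x axis). Summits within 1 kb make up 5.95% against 3.05% at random, and those over 100 kb away 15.3% against 36.4%.

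Peaks within 1 kb of a gene end had a lower fold than the rest, with a median of 5.79 against 6.53 (difference -0.744, permutation test over peaks with 100000 resamples, 2-sided p 0.0007). They nonetheless had more ChIP fragments at the summit, with a median of 28 against 20, over a higher background of 3.6 against 1.78 fragments. By q value, 8.92% (6.76 to 11.5) of peaks in the decile with the smallest q lay near gene ends, against 4.55% to 7.24% in the other deciles. The deciles were not tested against each other, and that interval overlapped the one of the next decile (5.29 to 9.63). With the ends of all annotated genes in place of protein-coding genes the difference was -0.224 and did not pass (p 0.1).

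Peak density differed between chromosomes. It was 2.20 peaks per Mb over the annotated spans of chromosomes 1 to 19, X and Y, highest on chromosome 13 at 3.46 (exact Poisson interval 3.13 to 3.82) and 0.680 (0.562 to 0.815) on X, and chromosome Y had 3 peaks. Unplaced or random contigs held 108 peaks on 11 sequences, and mitochondrial DNA held 7. Peaks with at least 200 fragments at the start of chromosome 9, from 2999998 to 3038364, and from 98662269 to 98665246 on chromosome 2 had backgrounds of 40.1 to 124 fragments and folds of 1.96 to 5.69.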

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

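All results on gene ends with their alternatives, contrasts between lists, 1 member per locus, 20 length bins and peaks over the lowest background were chosen only after the data were seen. Of 148 alternatives of results with a test, 130 kept their direction and side of the threshold, 7 no longer passed, 2 passed anew and 9 changed direction. Of 16 alternative numbers of lists above random, 13 stayed within 1.5 times. By construction, stricter selections lowered the number of peaks, to 3026 for those of smallest q and 1983 for those over the lowest background. The latter also set the share near gene ends at 2.41%, below random. That fall is built into the selection, which left out 86.7% of peaks near gene ends and 66.0% of the others, while random positions were not selected. From these fewer peaks, 6 lists in place of 10 lay above random, and 3 in place of 8 at gene ends. The lists lost were 4 of 20 follicular helper genes (adjusted p 0.055), 1 of 20 AP-1, NFAT and IRF factors (adjusted p 1), 3 of 24 cytokine genes (adjusted p 0.38) and 4 of 27 cell cycle genes (adjusted p 0.055). With the 3026 peaks, 4 of 20 AP-1, NFAT and IRF factors had a peak (adjusted p 0.095) and 4 gene-end lists passed. With the gene body alone 5 of 27 cell cycle genes had a peak (adjusted p 0.098), and with all annotated genes the fold difference near gene ends was -0.224 (p 0.1), where the cause was not tested. Lists that passed under no setting changed direction against random for Bcl6 co-repressors, to 0 of 20 with the 3026 peaks and 1 of 20 over the lowest background. The same held for B cell lineage genes, to 3 of 14 within 50 kb and 1 of 14 with the 3026 peaks, and for ribosomal protein genes, to 1 of 22 in the gene body alone, and the cause was not tested. In the gene body alone the share with a peak was higher than in effector genes by 42.8 percentage points for stem-like (adjusted p 0.0084) and 45.8 for exhaustion genes (adjusted p 0.0078), lists not matched on length. Exhaustion minus effector genes turned to -2.75 points within 50 kb and -5.95 over the lowest background, and stem-like minus exhaustion genes to -1.36 in the gene body, none past the threshold. Motifs, promoters by transcription start site, annotation classes, and overlap by any base for peak strength were planned and not run. No paired analysis was possible because each kind of library had 1 sample. Over the lowest background the fewest fragments at a summit in the list were 9, and whether fewer would have been called was not tested.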

Other observations

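The definition of runs of peaks, the count of runs over raised background, the genes singled out here, the test on ribosomal protein genes, the test without the tag and the test of Bcl6 cDNA copies present alike in both libraries were chosen only after the results were seen. Beside the fixed lists, 19 protein-coding genes had at least 10 peaks in the gene or 10 kb around it. Atxn1 had 21, with a highest fold of 43.0, Bach2 had 19, and Foxp1 and Dock10, a guanine nucleotide exchange factor of lymphocytes, had 18 each. Inpp4b, a phosphoinositide phosphatase gene, had 16, Lpp 15, and Maml2, a coactivator gene of the Notch pathway, 15 with a highest fold of 62.2. Cdk6 had 14, Cytip 13, Itpr1 and Nfkb1 12 each, and Bcl2 11. Several of these genes are long, with 415 kb for Atxn1 and 597 kb for Foxp1, while Cytip, which regulates lymphocyte adhesion, spans 66.4 kb and Nfkb1 107 kb.

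Summits were grouped along the genome. Runs of at least 4 summits no more than 10 kb apart numbered 144 and held 737 peaks (12.4%), against a mean of 0.107 runs and at most 2 in 1000 random placements. The longest had 18 peaks on chromosome 13 from 30600740 to 30658003, with its closest summit 2165 bp from Dusp22, and 18 on chromosome X from 126747056 to 126777948. A run of 14 peaks at 62804375 to 62839661 on chromosome 15, with folds up to 58.3, had Myc as its nearest protein-coding gene at a distance of at least 814160 bp, and Myc had no peak within 10 kb. Raised background over the genes, as the cause of most runs, predicted a higher median background in runs than at isolated peaks. The median background of called peaks was not higher in runs. It was 1.72 fragments in runs and 1.80 at isolated peaks (difference -0.0787, permutation p 0.03 with 100000 resamples). The permutation ran over peaks, and neighbours in a run are not independent, so this p may be too small. A raised background also makes a call harder, and only called peaks were compared. The values therefore describe called peaks and cannot exclude raised background as a cause. Raised input signal over part of the runs stays open for 3 of 144. Their median background lay above the middle 95% of isolated peaks, which ended at 8.92. It was 91.9 fragments on chromosome 9 from 2999998 to 3032994 and 91.9 on chromosome 2 from 98662269 to 98666511. On chromosome 17 from 35202018 to 35205442 it was 9.37. The median folds of these runs were 2.56, 2.38 and 3.42, and their 18 peaks are part of the counts above. Broad enriched stretches that the peak caller split could explain part of the runs: 34.2% of the gaps in runs were under 1 kb, between the bounds set for and against this before the test, so it stays open.

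T cell gene lists carried peaks more often than random lists matched on bins of gene length. Peaks at any highly expressed gene were examined with the ribosomal protein genes, of which 1 of 22 had a peak, against a random mean of 1.10. The interval of that share reached 22.8%, so an excess over random is not excluded. Expression was not measured here, and the bounds were set after the value was seen, so this explanation stays open. Neighbouring members that share peaks, such as Ccl3 and Ccl4, and coarse length matching are argued against. With 1 member per locus 10 of 10 lists stayed above random, and with 20 length bins 10 of 10. Open chromatin of T cell enhancers without Bcl6 may give peaks at the same genes, and 0 libraries of an HA ChIP from cells without the tag were among the samples, so binding by Bcl6 and signal from open chromatin cannot be told apart here. The level of the tagged protein against endogenous Bcl6 was not examined, and no biological explanation was tested.

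The peak at an end of Bcl6 may be binding to the endogenous gene or reads from the Bcl6 cDNA in the retrovirus. The background under it was 6.52 fragments, above the lowest background of 1.33, as the cDNA explanation predicted before the value was seen. That test separates little, since 306 of 353 peaks near gene ends (86.7%) also had a background above the lowest, with a median of 3.6, a comparison added after the value was seen. Copies of the cDNA present alike in ChIP and input would give a fold near 1. The fold was 6.92 with a lower limit of 5.18 and a −log10 q of 24.2. This test cannot decide, since a peak is in the list only if it was called over its background. Whether the input was the control is also not stated. Such copies, Bcl6 cDNA enriched with the tagged protein and binding to the endogenous gene stay open, and 0 other peaks lay inside the gene.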
